A study of Mus musculus with 6 samples.

How the data were processed

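Gene expression was measured in 6 pools of sorted myogenic (satellite) cells from male C57BL/6 mice aged 8 to 10 weeks, 3 pools from pharyngeal muscle and 3 from limb muscle (gastrocnemius and quadriceps). Per the labels, each pool held 150000 to 200000 cells collected from 10 to 30 mice, and total RNA went through 1 round of amplification before biotin labelling and hybridization to Illumina MouseWG-6 v2.0 arrays. The markers used for sorting are not given in the sources used here. All 6 arrays lay on 1 chip, the pharyngeal pools on the first 3 positions and the limb pools on the other 3, so that position on the chip and group cannot be told apart and no chip term could be fitted.

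The authors deposited unnormalized probe intensity values with a detection p-value for each probe and array, and a processed table of intensity values. Per the submitters' processing notes, GenomeStudio 2011.1 was used. The deposited detection p-values changed in steps of 1 in 936, and per the series' design text they are the share of negative control probes brighter than the probe. The series' design text names normalization with background correction, but the lowest unnormalized intensity per array lay between 76.1 and 82.1, and the processed intensities had nearly equal quartiles on all arrays (medians 99.5 to 99.6) and kept the ranks of the unnormalized values (Spearman's rho 1 across probes on each array), which fits quantile normalization without background subtraction. The unnormalized table was therefore analysed, and the processed table served as an alternative. Its scale was linear.

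The platform annotation names 1 gene for 34885 of 45281 probes and several for 18, and 10378 probes are unnamed here. Entrez identifiers of 34807 probes matched the reference gene table of the GRCm38.p6 assembly, which changed 0 symbols. The genome build behind the probe annotation is not given in the sources used here, and no coordinates are printed.

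Background was removed with limma 3.58.1 in R 4.3.3 by the normexp model, with the background read from the detection p-values and an offset of 16, followed by quantile normalization and log2. The offset draws dim values together, so that folds of dim genes are understated. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were kept (22633 probes). Each gene was represented by its brightest kept probe over the 6 arrays, which left 11262 genes, of which 4754 had several kept probes. Differences are pharyngeal minus limb on the log2 scale, from lmFit and eBayes with group as the only term (2-sided, prior degrees of freedom 3.44), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. SE is the moderated standard error. Each group had 3 arrays, and this number limits the precision. P-values measure the spread between pools of cells within a group.

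Where a gene's probe had a detection p under 0.05 on no array of a group, the fold is a bound. The mean of the brighter group was set against the dim group's mean of, per array, the higher of the lowest normalized value among probes with a detection p under 0.05 and the probe's own value. Such folds are written as at least N-fold. List means cover the members past the filter, with such genes at their fitted differences.

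Lists of genes (41) were written before the data were examined, and so were the rule for naming genes, the design and all alternatives but 1. The named genes are the 12 largest differences per direction among genes past the threshold with non-overlapping groups and a probe above background in both groups, without predicted genes; up to 6 per direction whose probe was above background in 1 group only, by the bound; up to 4 members past the threshold per list by smallest adjusted p; and any measured member of the lists of satellite cell markers, cranial mesoderm and somite and limb transcription factors and Hox genes, with Mki67, Hgf and Pabpn1. No probe used here is named for Mki67. Lists with at least 5 measured members (39) were tested against all other genes with camera (preset inter-gene correlation 0.01, 2-sided, Benjamini-Hochberg over these lists). Alternatives covered the background model, offset, normalization, the processed table, the filter, the variance model, array weights, the probe rule, a fold threshold, a replicate block, leaving out each array, an estimated inter-gene correlation and the self-contained test fry. The covariate chosen after the data were seen was the mean of the epithelial list on each array, centred within each group.

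The fit was tested on 20 simulated data sets with the means and residual spreads of the 11262 genes and 200 changed genes. It recovered 0.4% of genes changed by 0.5 on the log2 scale, 17.4% at 1, 70.4% at 2 and 88.0% at 3, with 4.72% false calls among all calls. A list of 20 genes shifted by 1 was called in 20 of the 20 sets, and an unshifted list in 0. Genes were simulated as independent, whereas the estimated correlation in the data was 0.218 for satellite cell and 0.898 for epithelial markers. These sets therefore do not give the rate of false list calls in the data.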

Results

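Expression profiles of satellite cells, the myogenic stem cells of skeletal muscle, were compared between pharyngeal and limb muscle, with 3 pools of sorted cells per group. The detection p-value was under 0.05 for 20919, 21742 and 22793 probes on the pharyngeal arrays and for 22060, 22241 and 22045 probes on the limb arrays. Across genes, correlations of log2 values were 0.959 to 0.968 between limb pools, 0.886 to 0.915 between pharyngeal pools and 0.858 to 0.885 between groups; genes are not independent replicates. The median within-group SD was 0.36 on the log2 scale in pharyngeal pools and 0.22 in limb pools. The first principal component, with 45.8% of the variance, separated the groups, and the second, with 23.6%, separated pharyngeal pool 1 from pharyngeal pools 2 and 3.

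**Figure D1:**
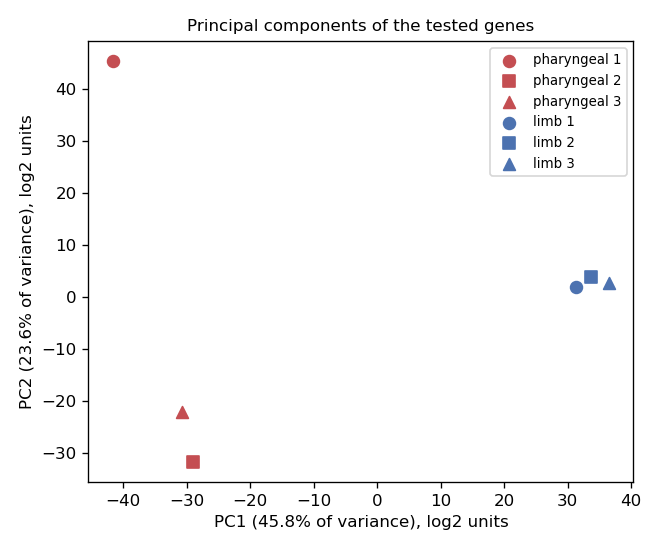
Scores of the 6 arrays on the first and second principal components of the tested genes, in log2 units, with red for pharyngeal and blue for limb pools. The limb pools lie close together and pharyngeal pool 1 lies apart from the other pharyngeal pools on the second component (23.6% of the variance).

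The comparison asked which genes distinguish satellite cells of pharyngeal muscle from those of limb muscle. Of 11262 genes tested, 374 differed (limma, adjusted p under 0.05), with 193 higher and 181 lower in the pharyngeal pools. The lower genes included Hox genes of the trunk and limbs, the transcription factors En1 and Lbx1, and the satellite cell markers Pax7, Myf5, Calcr and Cdh15. The higher genes included keratins, thyroglobulin (Tg), the chemokines Ccl2 and Cxcl2, the BMP antagonist Grem1 and the transcription factor Isl1. The groups did not overlap for any of the 374 genes; among all genes tested 26.7% did not overlap, against 10% by chance. Without limb pool 1, 2 or 3 the count was 80, 62 and 58 genes, with 38, 35 and 31 higher and 42, 27 and 27 lower, and without pharyngeal pool 2 the count of higher genes was 121. Of 88 named genes past the threshold, 33 passed in every fit without 1 pool in which they could be tested. Of these 33, 24 were tested in all 6 fits, and the others had no probe past the filter in some fits. Hoxc10 and Bpifb1, among the 24, were tested through another probe in the fits where their probe missed the filter. Named genes that did not pass in every such fit are given with their groups.

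Hox genes of paralogous groups 6 to 13, which give positional identity along the trunk and limbs, were lower in the pharyngeal pools. Of 10 measured members 8 fell and none rose, and 9 fell when adjusted over the list alone (mean difference -2.70, camera adjusted p = 1.56e-14). With an estimated correlation the adjusted p = 0.0638. Hoxc9 differed by -4.82 (SE 0.22, adjusted p = 0.000161), with means of 4.53 ± 0.33 in pharyngeal and 9.35 ± 0.08 in limb pools (log2, SD, n = 3). The probes of Hoxc9, Hoxa9, Hoxd9 and Hoxc12 were above background on 1 of 3 pharyngeal arrays, and that of Hoxc12 on 2 of 3 limb arrays, so that their fitted differences rest on levels near background. Hoxc6 was above background on no pharyngeal array and was at least 17.1-fold higher in limb pools (adjusted p = 0.000117). The probe used for Hoxc10 was also above background on no pharyngeal array, with a bound of at least 15.5-fold (adjusted p = 0.000115), although another probe of the gene was above background there. Hoxa11 and Hoxa10 were at least 4.45-fold and 3.90-fold higher in limb pools. Hoxa9, Hoxa7 and Hoxd8 differed by -2.65, -2.32 and -2.01, and the members that did not pass were Hoxd9 (-1.77, adjusted p = 0.0743) and Hoxc12 (-0.08, adjusted p = 0.873). All 8 genes passed in every fit without 1 pool in which they could be tested. Hoxc6, Hoxa10 and Hoxa11 could be tested in 3 of the 6 fits, as their probes missed the filter without a limb pool. Without a limb pool the Hoxc10 probe also missed the filter, and another probe of the gene was tested. With no filter on dim probes, which takes in members near background, the list mean was -1.11 (adjusted p = 3.76e-07). With probes above background on all 6 arrays too few members were left for the list test. On the same pharyngeal arrays epithelial markers were higher (mean 2.46) and tenocyte markers lower (mean -1.54).

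Of 6 measured Hox genes of groups 1 to 5, none passed over all genes, and 3 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.409, mean 0.23). The values were 1.31 for Hoxa2, 1.04 for Hoxb2, 0.84 for Hoxb3, 0.62 for Hoxb4 and -1.53 for Hoxa5. Hoxa5 was above background on 1 of 3 pharyngeal arrays and Hoxb4 on 1 of 3 limb and 2 of 3 pharyngeal arrays. Hoxc5, above background on no pharyngeal array, was at least 1.46-fold higher in limb pools (adjusted p = 0.0566, not past the threshold).

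Among 11 measured transcription factors of somites and limbs, 3 fell and none rose over all genes, and 4 fell and 1 rose when adjusted over the list alone (mean -1.05, camera adjusted p = 0.00451, adjusted p = 0.278 with an estimated correlation). En1, a homeobox gene of limb patterning, differed by -4.49 (SE 0.23, adjusted p = 0.000228). Lbx1, which marks limb muscle precursors during their migration, differed by -3.68 (SE 0.37, adjusted p = 0.0045), and Zic1 by -1.58 (SE 0.20). Zic1 did not pass without limb pool 1, 2 or 3 (highest adjusted p = 0.0638). Pax3 was -0.13, Meox2 -0.15, Tbx18 -0.06, Lmx1b -0.07, Sim2 -0.63, Shox2 -0.91, Tbx4 -0.86 and Tbx15 1.06, none past the threshold. The list test no longer passed when probes had to be above background on all 6 arrays (adjusted p = 0.415, the highest with the preset correlation, against a lowest of 0.00136). Lbx1, Zic1, Pax3, Lmx1b, Sim2 and Tbx4 were above background on 1 of 3 pharyngeal arrays and Pax3 and Lmx1b on 2 of 3 limb arrays, and the mean of the epithelial markers on the same arrays was higher by 2.46.

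Of 8 measured transcription factors of cranial mesoderm, 1 rose and 1 fell over all genes, and 3 rose and 2 fell when adjusted over the list alone (mean 0.30, camera adjusted p = 0.325). Isl1, a marker of the second heart field and pharyngeal mesoderm, rose by 2.19 (SE 0.26, adjusted p = 0.00737; adjusted p = 0.0601 without limb pool 3), and Ebf3 differed by -1.07 (SE 0.21, adjusted p = 0.0386). Ebf3 passed in 1 of 6 fits without 1 pool, that without pharyngeal pool 1 (highest adjusted p = 0.168). Tcf21, above background on no limb array, was at least 1.26-fold higher in pharyngeal pools (adjusted p = 0.143, not past the threshold). Tbx1 was 0.40, Ebf1 0.79, Hand2 0.47, Ebf2 -0.43 and Msc -0.60, none past the threshold. Isl1 and Hand2 were above background on 1 of 3 limb arrays, and Hand2 on 2 of 3 pharyngeal arrays.

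Satellite cell markers were lower in the pharyngeal pools. Of 18 measured members 8 fell and none rose, and 12 fell when adjusted over the list alone (mean -1.22, camera adjusted p = 9.52e-08, adjusted p = 0.354 with an estimated correlation). Pax7, the transcription factor that defines satellite cells, was 4.81-fold lower (-2.27, SE 0.33, adjusted p = 0.0144), and the myogenic factor Myf5 was 3.71-fold lower (-1.89, SE 0.27, adjusted p = 0.0133). The calcitonin receptor Calcr differed by -2.43 (SE 0.31, adjusted p = 0.0098), M-cadherin (Cdh15) by -2.29 (SE 0.28, adjusted p = 0.00799) and Chodl by -1.98 (SE 0.21, adjusted p = 0.0045). Ncam1 differed by -2.10, Fgfr4 by -2.20 and Chrdl2 by -1.46, with Fgfr4 above background on 1 and Ncam1 on 2 of 3 pharyngeal arrays. Chodl passed in each of 6 fits without 1 pool; without limb pool 2, Cdh15, Calcr, Myf5, Pax7, Ncam1, Fgfr4 and Chrdl2 did not, nor without limb pool 3 for all of these but Cdh15. Their highest adjusted p was 0.0624, 0.0649, 0.0892, 0.0900, 0.109, 0.188 and 0.177, in this order; Pax7, Ncam1, Fgfr4 and Chrdl2 also did not pass without limb pool 1, and Fgfr4 and Chrdl2 did not pass without some pharyngeal pools. With no filter on dim probes, over more genes, the adjusted p was 0.0504 for Pax7, 0.0588 for Ncam1, 0.125 for Fgfr4 and 0.0854 for Chrdl2. With a replicate block Myf5, Pax7, Ncam1, Fgfr4 and Chrdl2 did not pass. With cyclic loess it was 0.0564 for Fgfr4 and 0.0519 for Chrdl2, and with the epithelial covariate, chosen after the data were seen, 0.0508 for Fgfr4. Des, Sdc3, Sdc4, Itgb1, Itga7 and Met lay between -0.32 and 0.17, and Megf10 (-1.97, adjusted p = 0.0717), Cxcr4 (-1.09, adjusted p = 0.0772), Heyl (-0.95) and Vcam1 (-0.84) did not pass. Epithelial markers, described below, were higher on the same pharyngeal arrays (mean 2.46).

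Quiescence-associated genes were lower in the pharyngeal pools as well, with 6 of 16 measured members down, none up, and 8 down when adjusted over the list alone (mean -0.97, camera adjusted p = 3.13e-06, adjusted p = 0.278 with an estimated correlation). The growth arrest gene Gas1 differed by -2.19 (SE 0.19, adjusted p = 0.00305), Bmp6 by -1.64 (SE 0.21) and Tenm4 by -1.62 (SE 0.30). Bmp6 did not pass without limb pools 2 or 3, nor Tenm4 without any limb pool (highest adjusted p = 0.0734 and 0.163). Of the 16 members 4 are also satellite cell markers in the other list, Calcr among them, and the epithelial markers were higher on the same arrays (mean 2.46). Of 18 measured mitosis genes 2 rose and none fell, also when adjusted over the list alone (mean 0.53, camera adjusted p = 0.000771, adjusted p = 0.529 with an estimated correlation), and the list test did not pass without pharyngeal pool 3 (adjusted p = 0.0821, the highest with the preset correlation, against a lowest of 3.35e-05) or with fry (adjusted p = 0.225). The risen members were the centromere gene Cenpa (1.78, SE 0.29) and the anaphase activator Cdc20 (1.83, SE 0.33). Of 23 DNA replication genes 1 rose, Rrm1 (1.18, SE 0.19), over all genes and over the list alone (mean 0.12, camera adjusted p = 0.493). Among 18 CDK inhibitors and growth arrest genes 3 fell and 1 rose, and 6 fell and 1 rose when adjusted over the list alone (mean -0.33, camera adjusted p = 0.199; fry adjusted p = 0.0433). They were Gas1, Gas6 (-1.51) and Gadd45a (-1.40), and the stress gene Gadd45b (1.04) rose. Of the cell cycle genes named, Cenpa, Cdc20, Rrm1, Gas6, Gadd45a and Gadd45b each did not pass without 1 limb pool or more. Their highest adjusted p was 0.105, 0.154, 0.117, 0.116, 0.0941 and 0.186, in this order. Gadd45b passed in 0 of 6 fits without 1 pool. Cenpa also did not pass without pharyngeal pool 3, nor Cdc20 without pharyngeal pool 2. Without the filter on dim probes, the adjusted p was 0.0806 for Tenm4, 0.0586 for Cenpa, 0.0826 for Cdc20 and 0.0537 for Gas6, and Cdc20 had 0.0566 with the processed table and 0.0567 with no background model.

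Chemokine and cytokine genes were higher in the pharyngeal pools. Of 21 measured members 7 rose and none fell, and 10 rose and 1 fell when adjusted over the list alone (mean 0.80, camera adjusted p = 9.52e-08, adjusted p = 0.0638 with an estimated correlation). The neutrophil attractant Cxcl2 was 8.44-fold higher (3.08, SE 0.29, adjusted p = 0.00368), the monocyte attractant Ccl2 6.21-fold higher (2.64, SE 0.22, adjusted p = 0.00304), Lif 5.33-fold higher (2.41, SE 0.25) and Ccl7 2.97-fold higher (1.57, SE 0.21). Ccl2, Cxcl2 and Lif passed in each of 6 fits without 1 pool, and Ccl7 did not pass without limb pool 1, 2 or 3 (highest adjusted p = 0.0855). Ccl2 read 9.01 ± 0.06 in the pharyngeal pools and 6.38 ± 0.34 in the limb pools (SD, n = 3). Epithelial markers were higher on the same arrays (mean 2.46). Of 24 immediate early genes, which respond to tissue dissociation, 1 fell, Junb (-1.40, SE 0.24), also over the list alone (mean -0.14, camera adjusted p = 0.578). Of 14 heat shock genes none passed, also when adjusted over the list alone (mean 0.05, camera adjusted p = 0.597). Of 14 macrophage and myeloid markers 2 rose and none fell, and 4 rose when adjusted over the list alone (mean 0.79, camera adjusted p = 0.00411, adjusted p = 0.529 with an estimated correlation). They were S100a9, a neutrophil gene that stressed epithelia also express, at least 9.55-fold higher, and lysozyme Lyz1 (1.99, SE 0.41). The list test did not pass without pharyngeal pool 3 (adjusted p = 0.269, the highest with the preset correlation, against a lowest of 0.000784) or with fry (adjusted p = 0.275), and its mean was 0.51 with no filter on dim probes. Junb, S100a9 and Lyz1 did not pass without limb pool 1, 2 or 3 (highest adjusted p = 0.151, 0.113 and 0.179). Their adjusted p was 0.0536, 0.0806 and 0.123 with no filter on dim probes. S100a9 also did not pass with the processed table (adjusted p = 0.0675) or no background model (0.0676), nor Lyz1 with median scaling (0.0517).

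Epithelial markers were higher on the pharyngeal arrays, where 8 of 20 measured members rose and none fell, and 16 rose when adjusted over the list alone (mean 2.46, camera adjusted p = 1.02e-14, adjusted p = 0.446 with an estimated correlation). With fry the list's adjusted p was 0.0646. The basal keratin Krt14 was 45.9-fold higher (5.52, SE 0.39, adjusted p = 0.00152), Krt5 had a fitted difference of 5.06 (SE 0.52, adjusted p = 0.0045), and Krt13 was at least 21.9-fold higher. Esrp1 (3.23, SE 0.43) and Krt8 (2.05, SE 0.22) rose too. Of 5 measured thyroid and parathyroid markers 3 rose, also when adjusted over the list alone (mean 3.09, camera adjusted p = 4.99e-06, adjusted p = 0.376 with an estimated correlation). Thyroglobulin was at least 57.0-fold, chromogranin A (Chga) at least 9.40-fold and parathyroid hormone (Pth) at least 5.65-fold higher, each above background on no limb array. Chga and Pth did not pass without limb pool 1, 2 or 3 (highest adjusted p = 0.138 and 0.0671), and the thyroid and parathyroid list had too few members for its test without any 1 pharyngeal pool or with a stricter filter. With no filter on dim probes the mean of that list was 1.55 (adjusted p = 3.87e-05). Other genes with large increases were Ces1d (4.79), Wfdc2 (4.48), Ckmt1 (4.31), lactotransferrin (Ltf, 18.4-fold), Cyp2f2 (3.39), Adh7 (3.34) and Gsto1 (3.19), together with Krtdap (at least 22.4-fold), Tff2 (at least 16.7-fold) and Lipf (at least 16.7-fold). The probe of Bpifb1 read at least 44.2-fold higher (adjusted p = 5.48e-05), although another of its probes was above background in limb pools. Wfdc2, Ckmt1, Ltf, Cyp2f2, Adh7, Gsto1, Esrp1 and Lipf did not pass without 1 limb pool or more (highest adjusted p = 0.0671, 0.0634, 0.0618, 0.117, 0.165, 0.0967, 0.0671 and 0.0636). Without the filter on dim probes, the adjusted p was 0.0504 for Wfdc2, 0.0809 for Cyp2f2, 0.124 for Adh7, 0.0674 for Gsto1 and 0.102 for Chga. Adh7 and Chga also did not pass with an offset of 50 (adjusted p = 0.0675 and 0.0603), the processed table (0.0916 and 0.0682) or no background model (0.0920 and 0.0681). With probes above background on all 6 arrays, Ckmt1 was represented by another probe, with a difference of 1.14 (adjusted p = 0.0892). Tnfaip2 (4.15, SE 0.28) and Grem1 (3.37, SE 0.25) passed in each of 6 fits without 1 pool. The probes of Krt5, Esrp1, Krt8, Ces1d, Wfdc2 and Ckmt1 were above background on 1 of 3 limb arrays and those of Ltf, Tnfaip2 and Grem1 on 2 of 3, so that their fitted differences rest on limb levels near background. Krt14 was above background on all 3 limb arrays, but its limb mean of 4.73 lay below that of Ltf (4.82). Its fold therefore also rests on limb levels near background. The mean of the epithelial list was 6.52, 7.01 and 8.58 on pharyngeal arrays 1, 2 and 3.

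Tenocyte markers were lower in the pharyngeal pools, on whose arrays epithelial markers were higher (mean 2.46), with 5 of 11 measured members down, none up, and the same counts when adjusted over the list alone (mean -1.54, camera adjusted p = 2.68e-05, adjusted p = 0.376 with an estimated correlation). The matrix proteoglycans Kera and Fmod differed by -3.51 (SE 0.42) and -3.32 (SE 0.35), and Comp and Thbs4 by -2.69 and -1.94. Kera, Comp, Thbs4 and Neu2 did not pass without 1 limb pool or more (highest adjusted p = 0.0507, 0.0892, 0.0671 and 0.0897). Without the filter on dim probes, the adjusted p was 0.0872 for Comp and 0.0600 for Neu2. Other large decreases were Dclk3 (-3.49), the muscle cofactor Vgll2 (-3.14), Hsd11b1 (-3.05), Kng1 (-2.92) and Neu2 (-2.77). Kera was above background on 2 of 3 pharyngeal arrays, and Vgll2 and Kng1 on 1 of 3. The probes used for Mlxipl and Col22a1 were above background on no pharyngeal array and read at least 4.80-fold and 3.75-fold higher in limb pools, although another probe of each gene was above background in pharyngeal pools. Mlxipl did not pass without limb pool 1, 2 or 3 (highest adjusted p = 0.264). In those fits its probe missed the filter and another probe of the gene was tested, so the loss does not show dependence on a pool. Oxidative phosphorylation genes had a mean of -0.32 over 50 members and ribosomal protein genes of -0.28 over 47, with no single member past the threshold, also when adjusted over each list alone. Their camera adjusted p-values were 0.000415 and 0.00348, against 0.668 and 0.737 with an estimated correlation (adjusted p), and ribosomal protein genes did not pass without pharyngeal pool 2 (adjusted p = 0.0728, the highest with the preset correlation, against a lowest of 1.80e-06). With fry their adjusted p-values were 0.107 and 0.224.

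**Figure D2:**
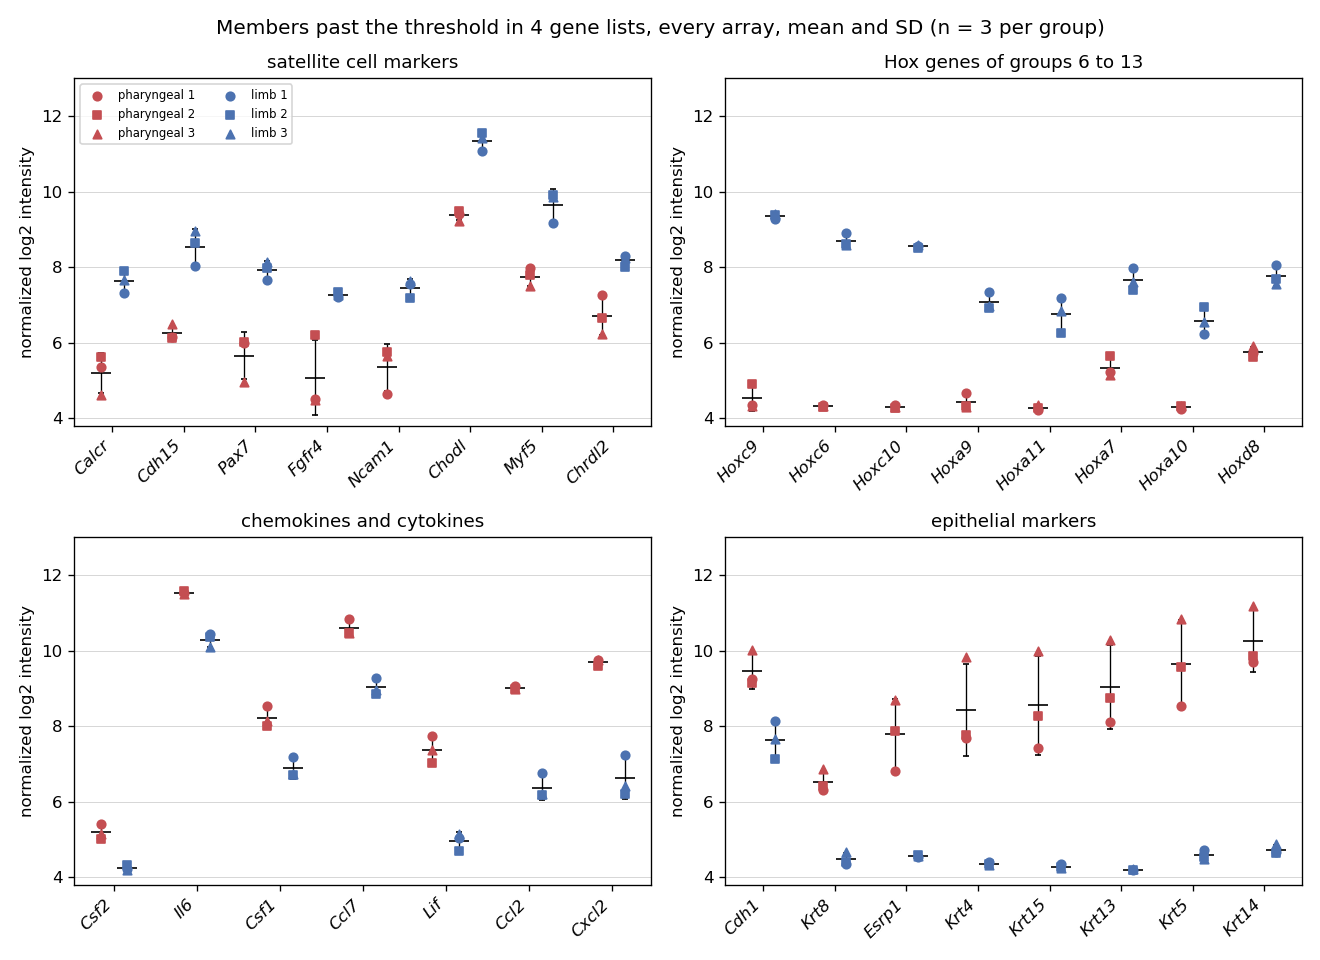
Normalized log2 intensity of every list member past the threshold in 4 gene lists, with each pool as a symbol, red for pharyngeal and blue for limb, and bars for the mean and SD (n = 3). Epithelial markers are brightest on pharyngeal array 3, while Ccl2 reads 9.01 ± 0.06 across the pharyngeal arrays.

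Fibroblast, endothelial, pericyte, Schwann cell, cartilage and adipocyte markers did not pass as lists, unlike the macrophage and tenocyte markers above, and endothelial markers passed without pharyngeal pool 3 (adjusted p = 0.00788) and without limb pool 2 (adjusted p = 0.0307), in a range of 0.00788 to 0.923 over alternatives. The camera adjusted p was 0.578 for fibroblast markers (mean -0.12, 18 members, 1 up, Has1 at 1.18), 0.167 for endothelial markers (mean -0.50, 18 members, none past the threshold), 0.384 for pericyte and smooth muscle markers (mean 0.08, 15 members, 2 up, Actg2 at 1.26 and Higd1b at 1.08), 0.578 for Schwann cell markers (mean 0.13, 12 members, none past) and 0.578 for cartilage markers (mean -0.36, 10 members, 2 down, Comp and Chad, the latter above background on 2 of 3 pharyngeal arrays). Counts adjusted over each list alone were the same for these lists. Adipocyte markers had a mean of -0.21 over 6 members (camera adjusted p = 0.384), with Pparg up (1.42) and Cd36 down (-1.09) and 1 up and 2 down when adjusted over the list alone. Has1, Actg2, Higd1b, Chad, Pparg and Cd36 did not pass without limb pool 1, 2 or 3. Their highest adjusted p was 0.185, 0.140, 0.177, 0.124, 0.175 and 0.163, in this order. Of 6 fits without 1 pool Higd1b passed in 0, Has1, Chad, Pparg and Cd36 in 1 and Actg2 in 2. With no filter on dim probes the adjusted p was 0.0560 for Has1, 0.0576 for Higd1b, 0.0872 for Comp, 0.0952 for Chad and 0.0780 for Pparg. Chad and Pparg did not pass with an offset of 50 (adjusted p = 0.0546 for both), the processed table (0.0717 and 0.0703) or no background model (0.0716 and 0.0705). Chad did not pass with array weights (0.0512) or median scaling (0.0507), nor Higd1b with array weights (0.0533) or eBayes trend and robust fitting (0.0521). Lymphocyte markers (4 measured, mean 0.13) and erythroid markers (3 measured, mean -0.38) were too few for the list test, and no member passed.

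Among 14 mature myofibre genes, Tnni2 (2.12, SE 0.29) and Myh1 (2.12, SE 0.32) rose and Atp2a1 (-1.58, SE 0.24) fell, while 5 rose and 3 fell when adjusted over the list alone (mean 0.31, camera adjusted p = 0.357). Tnni2, Myh1 and Atp2a1 did not pass without 1 limb pool or more (highest adjusted p = 0.0722, 0.101 and 0.109). The adjusted p of Myh1 was 0.0553 with no filter on dim probes. None of 12 myogenic commitment factors passed over all genes, and 3 fell when adjusted over the list alone (mean -0.55, camera adjusted p = 0.192; adjusted p = 0.0202 without pharyngeal pool 2, the lowest with the preset correlation, against a highest of 0.305). None of 16 sarcomeric and differentiation genes passed over all genes, and 2 rose when adjusted over the list alone (mean -0.09, median 0.01, camera adjusted p = 0.67, direction up). Hgf, the growth factor that activates satellite cells, differed by -0.02 (adjusted p = 0.979, above background on 2 of 3 pharyngeal arrays) and Pabpn1, mutated in oculopharyngeal muscular dystrophy, by -0.03 (adjusted p = 0.954).

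**Figure D3:**
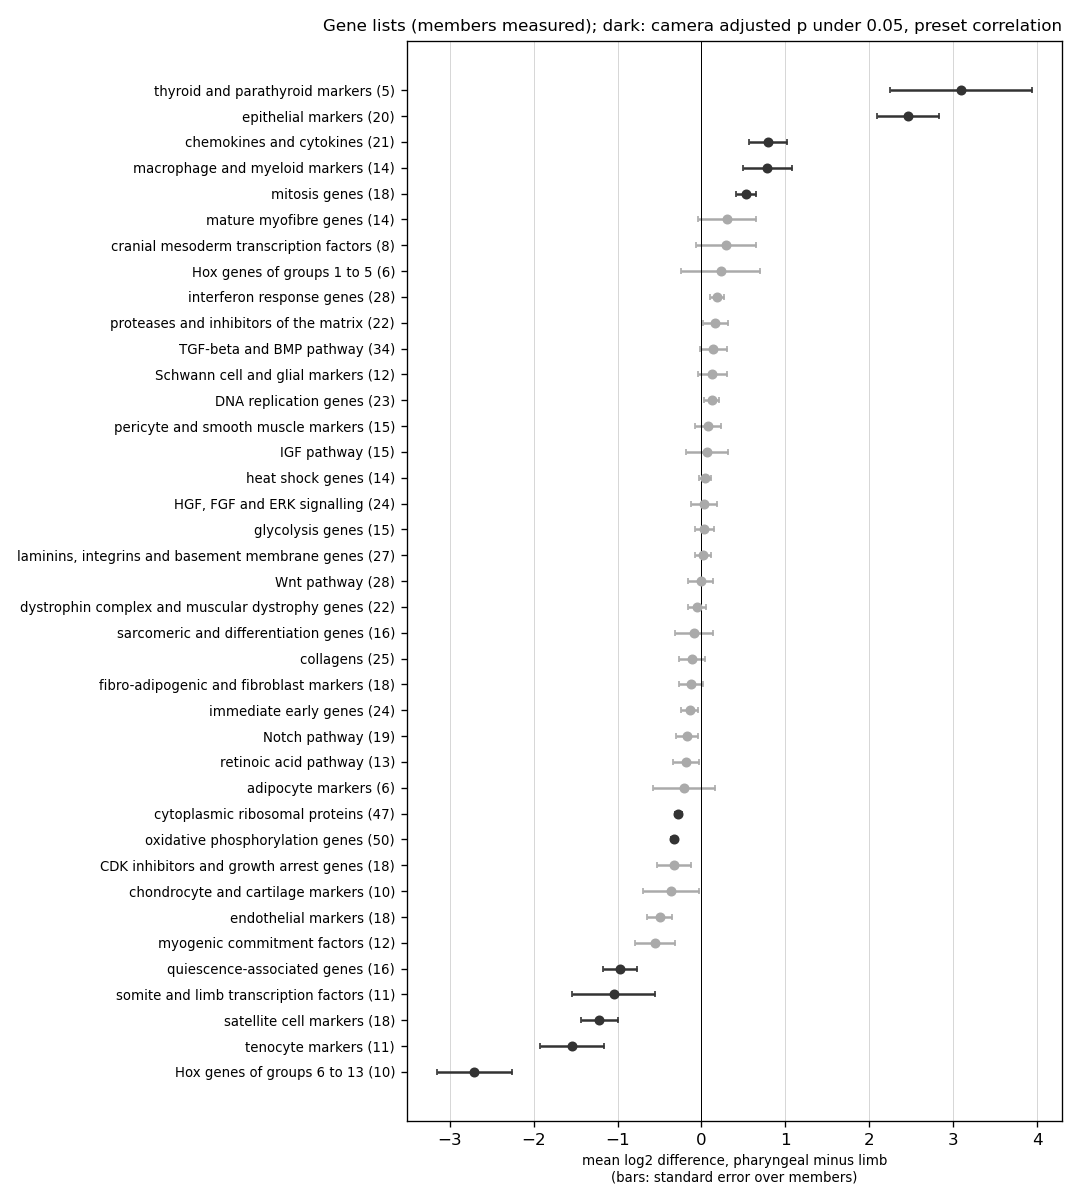
Mean log2 difference, pharyngeal minus limb, of the measured members of each of 39 gene lists, with bars for the standard error over members and dark symbols for a camera adjusted p under 0.05 with the preset correlation. Over members past the detection filter, Hox genes of groups 6 to 13 have a mean of -2.70 and thyroid and parathyroid markers of 3.09; with no filter the means are -1.11 and 1.55.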

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

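The test with the covariate below was chosen after the data were seen; all other settings were chosen before the data were examined. No named gene or list past its threshold in any setting changed direction, and those of the 374 genes that were still tested kept their sign in each setting that refitted genes (250 with probes above background on all 6 arrays, 334 to 356 without 1 pool). Counts stayed within 1.5 times of 374 genes (278 to 481) with no background model, an offset of 50, cyclic loess, median scaling, the processed table, no filter, both stricter filters and array weights, and 353 genes also reached a 2-fold difference. Similar counts did not mean the same genes. Of the 374 genes, 233 still passed with no filter, 310 with no background model and 311 with the processed table. The number was 322 with median scaling, 338 with an offset of 50, 341 with cyclic loess and 360 with array weights. With probes above background on all 6 arrays 245 of the 250 still tested passed. The processed table, with its background not subtracted, gave smaller list means (1.35 for epithelial markers, -1.40 for Hox genes of groups 6 to 13). With eBayes trend and robust fitting 568 genes differed, 307 of them higher. With every probe counted on its own 569 probes differed, 285 of them lower. This fit took all probes past the filter, with or without a gene name, and genes can have several probes. With the covariate 579 genes differed, 310 of them higher. The covariate was centred within each group, so it could change only the residual spread and not the fitted differences (median -0.0563 with and without it). It therefore does not adjust the differences between groups for epithelial RNA. The cause of the larger count under trend was not tested.

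Leaving out 1 array gave 58 to 360 changed genes, 31 to 148 higher and 27 to 212 lower, with fewer samples in each fit; the lowest counts were without a limb array, and why these moved the count more than pharyngeal arrays was not tested. Lists past the threshold numbered 11 to 13 in these fits, 0 with an estimated correlation and 7 when probes had to be above background on all 6 arrays, a filter that leaves fewer members. With fry 8 lists passed. Among genes given above or below with limb pools only, Comp, Cyp2f2, Adh7, Junb, Lyz1, Hey1, Wif1, Plaur, Gbp2 and Col15a1 also failed without 1 pharyngeal pool or more. Of 122 named genes over 18 settings, 291 of 2084 values no longer passed, 11 newly passed, and 21 values past no threshold in either fit changed sign; 32 such list means did so.

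The titles share replicate numbers across groups. Same-numbered deviations from the group means correlated at -0.01, -0.01 and 0.00 across genes, so the values showed no pairing. Whether same-numbered pools were prepared together is not given in the sources used here. With a replicate block 139 genes differed, 74 higher and 65 lower, with fewer residual degrees of freedom, and 12 lists passed. Of the 374 genes 136 still passed. Of 122 named genes 35 no longer passed. They included Pax7, Myf5, Ncam1, Fgfr4, Chrdl2, Bmp6, Tenm4, Ebf3, Atp2a1, Rrm1, Cenpa, Cdc20, Gadd45a, Gas6, Gadd45b, Junb, Hey1, Wif1 and Plaur. The rest were Gbp2, Col15a1, Col19a1, Adamts4, Has1, Actg2, Higd1b, S100a9, Lyz1, Thbs4, Chad, Chga, Cyp2f2, Adh7, Cd36 and Pparg. Signal close to background limits the precision of dim genes, whose folds are understated.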

Other observations

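All tests of explanations below and the epithelial covariate were chosen after the results were seen; the splits of the arrays were planned. Signalling genes moved in both directions. Of 34 measured TGF-beta and BMP pathway genes 3 rose and 3 fell, and 5 rose and 3 fell when adjusted over the list alone (mean 0.14, camera adjusted p = 0.192; adjusted p = 0.0462 without pharyngeal pool 3, the lowest over alternatives, against a highest of 0.692). Among called members, the extracellular antagonists Grem1 (3.37), Fst (1.92, SE 0.25, adjusted p = 0.0104) and Fstl3 (0.99, adjusted p = 0.0439) rose. Chrdl2 (-1.46, adjusted p = 0.042), another antagonist, fell. Fstl3 was named and this grouping was made after the values were seen, and antagonists that did not pass were not counted. The fits without 1 pool were not examined for Fstl3. The ligands Bmp4 (-2.15, SE 0.35, adjusted p = 0.0222) and Bmp6 (-1.64) fell. Of 28 Wnt pathway genes the receptor Fzd2 (-1.73) and the inhibitor Wif1 (-1.92) fell and none rose, and 3 fell and 2 rose when adjusted over the list alone (mean -0.01, median 0.02, camera direction up, adjusted p = 0.637). Of 19 Notch pathway genes the target Hey1 (-1.27, SE 0.26) fell and none rose, also over the list alone (mean -0.17, camera adjusted p = 0.59). Among 24 genes of HGF, FGF and ERK signalling Plaur (1.21) rose and Fgfr4 (-2.20) fell, and 2 rose and 1 fell when adjusted over the list alone (mean 0.03, median -0.02, camera direction up, adjusted p = 0.572). Fst, Chrdl2, Bmp4, Bmp6, Fzd2, Wif1, Hey1, Plaur and Fgfr4 did not pass without 1 limb pool or more (highest adjusted p = 0.0722, 0.177, 0.120, 0.0734, 0.109, 0.172, 0.195, 0.164 and 0.188), while Grem1 did. Wif1 was above background on 1 of 3 pharyngeal arrays. Without the filter on dim probes, the adjusted p was 0.0680 for Bmp4, 0.0528 for Fzd2, 0.123 for Wif1, 0.0861 for Hey1, 0.0854 for Chrdl2 and 0.125 for Fgfr4. Wif1 also did not pass with no background model, an offset of 50, cyclic loess, median scaling, the processed table or array weights (adjusted p = 0.0737, 0.0619, 0.0578, 0.0625, 0.0738 and 0.0629). Hey1 did not pass with cyclic loess (0.0564), median scaling (0.0507) or the epithelial covariate (0.0521), Chrdl2 and Fgfr4 with cyclic loess (0.0519 and 0.0564), Fgfr4 with the covariate (0.0508), nor Plaur with eBayes trend and robust fitting (0.0551).

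Of 28 interferon response genes Gbp2 (1.44, SE 0.26) rose, also over the list alone (mean 0.19, camera adjusted p = 0.0585; adjusted p = 0.0184 without pharyngeal pool 1, 0.0346 without pharyngeal pool 2, 0.0414 without limb pool 1 and 0.0323 with array weights, with a range of 0.0184 to 0.394 over alternatives). Of 25 collagens Col15a1 (-1.14) and Col19a1 (at least 2.39-fold lower) fell, and 2 fell and 1 rose when adjusted over the list alone (mean -0.11, camera adjusted p = 0.602). Of 22 proteases and inhibitors of the matrix Adamts4 (1.21) rose, and 4 rose and 2 fell when adjusted over the list alone (mean 0.17, camera adjusted p = 0.247). Gbp2, Col15a1 and Adamts4 did not pass without limb pool 1, 2 or 3 (highest adjusted p = 0.154, 0.186 and 0.125). Without the filter on dim probes, the adjusted p was 0.0631 for Gbp2 and 0.0600 for Col15a1, which also did not pass with cyclic loess (0.0524) or median scaling (0.0507). No gene passed over all genes in the IGF (mean 0.06, median -0.03, camera direction down, adjusted p = 0.943), retinoic acid (mean -0.18, adjusted p = 0.578), basement membrane (mean 0.02, median -0.04, camera direction up, adjusted p = 0.763), glycolysis (mean 0.03, median -0.03, camera direction up, adjusted p = 0.637) or dystrophin complex lists (mean -0.05, adjusted p = 0.844), with 15, 13, 27, 15 and 22 measured members in this order. When adjusted over the list alone, 2 rose and 2 fell in the IGF list, 1 rose in the retinoic acid list, 1 rose in the basement membrane list, 1 rose and 1 fell in the dystrophin complex list and none passed in the glycolysis list.

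The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 374 genes, 193 higher and 181 lower, and the highest other split 0 in each count. For lists the real split gave 12 and the other splits 3 to 11. With the preset correlation the list test thus called lists in every mixed split, although no gene passed there. The mixed splits are not balanced for group, so these counts are not a rate of false list calls. In each count 1 of the 10 splits, the real one, was as large.

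Epithelial, thyroid and parathyroid transcripts were raised on the pharyngeal arrays. The ratio of the median unnormalized signals, pharyngeal over limb, was 1.05, against a mean 5.52-fold difference of the epithelial list. These medians (95.4 to 105.5) lay near background and the arrays were quantile normalized. The ratio is thus a weak test of overall signal as a source. A candidate source is RNA of epithelial and glandular cells in the pharyngeal pools. Pools with different shares of such cells would make 1 array brightest for most members. Of the 20 measured epithelial members 20 had their highest pharyngeal value on the same array, pharyngeal 3. Krt14 and Tg, both abundant in their cells of origin, read 10.25 and 10.42 on the pharyngeal arrays. Of the glandular markers named, Tg and Pth were also highest on pharyngeal array 3, but Chga on array 2 (6.13, 8.68 and 8.66 on arrays 1 to 3). Expression of these genes by pharyngeal satellite cells, the difference that the design names, was not tested, and the sort gate is not given in the sources used here.

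Satellite cell and quiescence-associated genes were lower on the same arrays. Dilution by epithelial RNA as the only change would lower fibroblast markers alike, but their list mean lay 1.09 above that of the satellite markers (SE 0.265 over members). Members are not independent (estimated correlation 0.218 for satellite and 0.266 for fibroblast markers). The SE is therefore too small, and this difference does not exclude dilution. Of the 8 satellite markers past the threshold, Pax7, Myf5, Calcr, Chrdl2, Chodl and Fgfr4 were lowest on pharyngeal array 3, the brightest for epithelial members. Cdh15 was highest there and Ncam1 was lowest on array 1. Whether these differences between 3 arrays follow dilution was not tested. A lower share of satellite cells with every other cell type raised alike would raise both epithelial and tenocyte markers. The epithelial list mean lay 4.01 above that of tenocyte markers (SE 0.530, also over members). Both list means were known when this test was chosen. Members are correlated here too (estimated correlation 0.898 for epithelial and 0.272 for tenocyte markers), so this SE is also too small. Tenocyte markers were lower rather than higher (5 of 11 down, none up), which goes against that form of the explanation. RNA from several other cell types at once remains open. More frequent cycling of pharyngeal satellite cells may also contribute, but the DNA replication list mean was 0.12 (SE 0.0920 over members) while mitosis genes passed with the preset correlation only (adjusted p = 0.529 with an estimated correlation, 0.225 with fry and 0.0821 without pharyngeal pool 3), so it stays open with the muscle of origin.

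Chemokine and cytokine genes were higher on the pharyngeal arrays. If RNA varying with the epithelial list mean carried them, the 7 genes past the threshold would follow that mean across the 3 pharyngeal arrays. Their slope would be near 0.694, the share of their signal in excess of limb, and the mean slope was -0.0658 (SE 0.0231 over genes). All 7 slopes rest on the same 3 arrays, so the SE over genes does not measure the error of the slope. Krt8, an epithelial member, went from 6.30 to 6.86 between pharyngeal arrays 1 and 3, against 6.52 to 8.58 for the list mean. Epithelial or glandular RNA that does not follow the list mean was therefore not excluded. A stronger immediate early response to dissociation would raise immediate early genes, whose list mean was -0.14 (SE 0.100). Their mean levels were 9.72 in pharyngeal and 9.86 in limb pools. Each pool was measured once, so a later or longer stress response was not tested. Which cells of the pools carried these transcripts was not tested, and muscle of origin and position on the chip cannot be told apart.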
